A study of Mus musculus with 13 samples.

How the data were processed

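The samples were 11 expression arrays of jejunal epithelium (4 control, 3 Cdx2 knockout, 4 compound Cdx2 and Cdx1 knockout), 1 Cdx2 ChIP-seq library of jejunal villus cells and 1 input DNA library, all from mice of a mixed strain. For ChIP, per the labels, villus cells were fixed in 1% formaldehyde for 15 min at 4 °C and 35 min at 25 °C, and libraries were made from 10 ng of DNA. Groups were taken from the labels. The array values are log2 expression per transcript, deposited by the authors after RMA, which corrects background, normalizes across arrays and summarises probes, from Affymetrix mouse arrays. The version of the probe sets and of RMA is not given in the sources used here. The authors' deposited table holds, per the file headers, log2 fold changes, t statistics as a score, and p-values with false discovery rates from limma for the compound knockout, with the number and distance of Cdx2 peaks per transcript. Its largest difference from the log2 changes computed here was 0.005.

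Reads were mapped with ELAND and peaks called with MACS at a p-value threshold of 1e-05, per the file headers, on mouse build mm9, per the labels. The deposited peak list gives, per the file headers, the count of tags in each peak, a score that rises with the negative logarithm of the p-value, the fold enrichment over the local input background, and a false discovery rate in percent from swapping ChIP and input. MACS used a fragment length of 181 bp and an effective genome size of 2.5e+09, per the file headers. Versions of ELAND and MACS are not given in the sources used here. The deposited read files hold 1 uniquely mapped read of 40 bp per line. Reads were shifted by 90 bp and counted in the authors' peaks, with Wilson intervals for shares at the 95% level. A reference genome and a gene annotation were not used here, so motifs and positions within genes were not analysed here.

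Of 22587 features 64 array control features were left out of the tests. Of the 22523 others, 18294 were named by their accession, 805 only by the authors' deposited table, and 3424 had no name. The feature with the highest mean over all arrays was kept per gene, which left 16213 genes with a symbol and 19637 entries. Values of 7328 features equal those of another feature on all arrays, since transcripts can share probes, and entries held 17563 distinct profiles. A single linear model with a term for each of the 3 groups was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and Benjamini-Hochberg adjustment over all entries, and an adjusted p under 0.05 was called. Standard errors are those of the limma contrast. Replicate numbers were checked for pairing by the correlation of deviations from the group means. Between control and Cdx2 knockout arrays of the same number it was 0.281, 0.119 and 0.575, all above 0.1. These were treated as pairs in a refit with a block and in the choice of splits, while the main fit held no term for pairs. The pairing comes from the values and not from the labels, and control array 1 with Cdx2 knockout array 2, of unlike numbers, gave 0.316. The correlation was not above 0.1 for every pair in the other 2 contrasts. The fit with the block held all 3 groups. The groups, the tests, the gene lists, the rule for naming genes and the first set of alternatives were fixed before the data were examined.

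Gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over 32 lists per contrast, and again with an estimated correlation, and with fry. The lists were brush border and digestion, nutrient transport, lipid absorption, mineral absorption, ileal bile acid, goblet, Paneth, enteroendocrine, tuft, crypt and stem cell, cell cycle, gastric and foregut, squamous and oesophageal, colon, intestinal transcription factors, junctions and adhesion, xenobiotic metabolism, fatty acid oxidation and ketogenesis, cholesterol synthesis, oxidative phosphorylation, endoplasmic reticulum stress, inflammation and antimicrobial, interferon response, T lymphocyte, B and plasma cell, myeloid, stroma and muscle, endothelium, exocrine pancreas, erythroid, sex check and Hox clusters. Of 650 list members 592 were measured.

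Genes were named by rule. The rule covers Cdx1 and Cdx2 always, and per contrast the 8 largest rises and the 8 largest falls among called genes with a symbol whose arrays did not overlap between the groups. It further covers up to 4 called members per list with the largest changes, the largest differences between the knockouts, the 8 largest falls and 4 largest rises with a peak in the compound knockout, and 10 peaks. Xist and the 18S features were reported as checks on the arrays, chosen after their values were seen. A result for 1 gene that the rule covers is not reported here.

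Overlap and correlation of the 2 knockouts against the same controls were set against 100 simulated data sets of unchanged groups and against controls split 2 against 2. The share of large compound changes seen in the Cdx2 knockout was, after seeing the data, set against split controls and against 100 simulations that kept the compound changes and left the Cdx2 knockout unchanged. Peaks near changed genes were tested by two-sided Fisher's exact tests over 15816 entries with a peak assignment by the authors, of which 3183 had a peak within 20 kb, and by the Mantel-Haenszel odds ratio within 5 quintiles of mean level. Listed distance and listed peak number differ for 40 and 38 features. On simulated data with 100 genes changed by a log2 of 1, the fits recovered 85%, 86% and 87% of them in the 3 contrasts, and of genes changed by 0.5 they recovered 31%, 44% and 45%. Alternatives were a replicate block, normalization again, centring, a filter on dim features, all features, 2-group fits, array weights, a prior with a trend, other thresholds, other peak distances and leaving out each array. Added after seeing the data were a term for sex, arrays with Y-linked signal alone, leaving out 2 arrays with raised 18S, counting identical values once, and counting a peak at any transcript of a gene. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for reads, peaks and figures.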

Results

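RNA was measured on 11 expression arrays of mouse jejunal epithelium, the absorptive lining of the middle part of the small intestine. Binding of Cdx2, a homeobox transcription factor of the intestinal epithelium, was mapped by ChIP-seq in jejunal villus cells. The arrays were 4 littermate controls, 3 labelled as Cdx2 knockout and 4 labelled as compound knockout of Cdx2 and the related factor Cdx1. All array mice received 1 mg of tamoxifen a day for 5 days, and the epithelium was taken 4 days later. Nothing in the labels says that the arrays of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. Array medians lay between 7.35 and 7.42 on the log2 scale, and the number of arrays limits the precision. The ChIP library held 5949008 mapped reads of 40 bp and the input DNA library 6445623, with 1 library of each and no replicates.

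Across genes, which are not independent replicates, Pearson correlations between arrays were 0.973 to 0.99 among controls, 0.981 to 0.988 among Cdx2 knockouts and 0.98 to 0.991 among compound knockouts. Between controls and Cdx2 knockouts they were 0.955 to 0.97, and between controls and compound knockouts 0.9 to 0.917. The first principal component held 63.1% of the variance, with scores of -52.30 to -46.62 for controls, -16.32 to -8.27 for Cdx2 knockouts and 56.91 to 63.27 for compound knockouts. Control features for 18S ribosomal RNA averaged 7.61 ± 0.20 (SD, n = 4) in controls, while Cdx2 knockout array 3 read 10.32 and compound array 4 read 9.07. All 4 control arrays carried Y-linked signal. Xist, the RNA of the inactive X chromosome, was high in Cdx2 knockout array 1 and in compound arrays 1, 2 and 3, at 10.12 to 10.60, against at most 6.66 in controls. Sex was thus unequal between the groups.

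The first comparison asked whether the targeted transcripts were lower in the knockouts. Cdx1 averaged 9.76 ± 0.21 (SD, n = 4) in controls, 9.91 ± 0.11 (n = 3) in Cdx2 knockouts and 8.46 ± 0.21 (n = 4) in compound knockouts. In the compound group Cdx1 fell by 1.30 ± 0.13 (SE) on the log2 scale (adjusted p = 1.78e-05, limma with Benjamini-Hochberg), with all 4 arrays below all 4 controls. The difference between Cdx2 knockouts and controls was 0.15 (adjusted p = 0.731, limma). The Cdx2 transcript read 9.25 to 9.71 in controls, 9.63 to 10.49 in Cdx2 knockouts and 9.42 to 10.18 in compound knockouts. Its log2 difference from controls was 0.65 ± 0.24 in the Cdx2 knockout (adjusted p = 0.172) and 0.31 ± 0.22 in the compound knockout (adjusted p = 0.325, limma). The Cdx2 feature was therefore not lower in arrays labelled as Cdx2 knockout, and it does not check the label. Neither the position of its probes nor the deleted part of the gene is given in the sources used here.

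The second comparison asked what differed in arrays labelled as Cdx2 knockout. In the 3 Cdx2 knockout arrays, against 4 controls, 10 of 26 brush border genes fell, 9 of 22 gastric genes rose and 14 of 22 cholesterol synthesis genes rose. The camera calls of these 3 lists were lost with an estimated correlation, at adjusted p = 0.165, 0.111 and 0.132. Lct, the lactase of the brush border, fell by 3.64 ± 0.25 on the log2 scale (SE; adjusted p = 1.11e-05, limma with Benjamini-Hochberg). Gkn3, a secreted protein of the gastric mucosa, rose by 3.15 ± 0.37 (adjusted p = 0.000413, limma), and Cyp51, a demethylase of sterol synthesis, rose by 1.65 ± 0.21 (adjusted p = 0.000876, limma). Gip, an incretin hormone of enteroendocrine cells, fell by 2.13 ± 0.28 (adjusted p = 0.000897, limma). Of 19637 entries tested, 1257 passed the threshold (6.4%), 662 higher and 595 lower, and 3342 had an unadjusted p under 0.05. At least 2-fold changes were 295 up and 237 down. The median absolute log2 change of called entries was 0.89, and the median standard error over all entries was 0.121.

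Among entries with a gene symbol whose arrays did not overlap between the groups, the largest rise was that of Ttr, the carrier of thyroxine and retinol-binding protein, at 7.14 ± 0.22. Sult1c2, a sulfotransferase, rose by 5.66 ± 0.22, Lyve1, a hyaluronan receptor, by 5.43 ± 0.30, Gml2 by 5.39 ± 0.32, and Ly6d by 5.32 ± 0.30. Cyp2d10, a cytochrome P450, rose by 5.12 ± 0.34, Pdk4, an inhibitory kinase of pyruvate dehydrogenase, by 5.03 ± 0.73, and S100g, the calcium-binding protein calbindin-D9k, by 4.89 ± 0.94. The largest falls were those of Dnase1, a secreted nuclease, at -6.04 ± 0.18, and Reg3a, an antimicrobial lectin, at -5.34 ± 0.25. Gsdmc2, a gasdermin, followed at -5.09 ± 0.65, and its values equal those of an unnamed entry. Next came Car4, a membrane carbonic anhydrase, at -4.75 ± 0.64, Slc13a1, a sulfate transporter, at -4.72 ± 0.68, and Abcb1a, a drug efflux pump, at -4.54 ± 0.66. Tmigd1 stood at -4.53 ± 0.32 and Bcl2l15 at -4.51 ± 0.26. Adjusted p over these 16 genes ran from 2.44e-08 for Ttr and Dnase1 to 0.00875 for S100g (limma with Benjamini-Hochberg). The call for S100g ended when the 2 arrays with raised 18S were left out (adjusted p = 0.0548, limma).

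**Figure D1:**
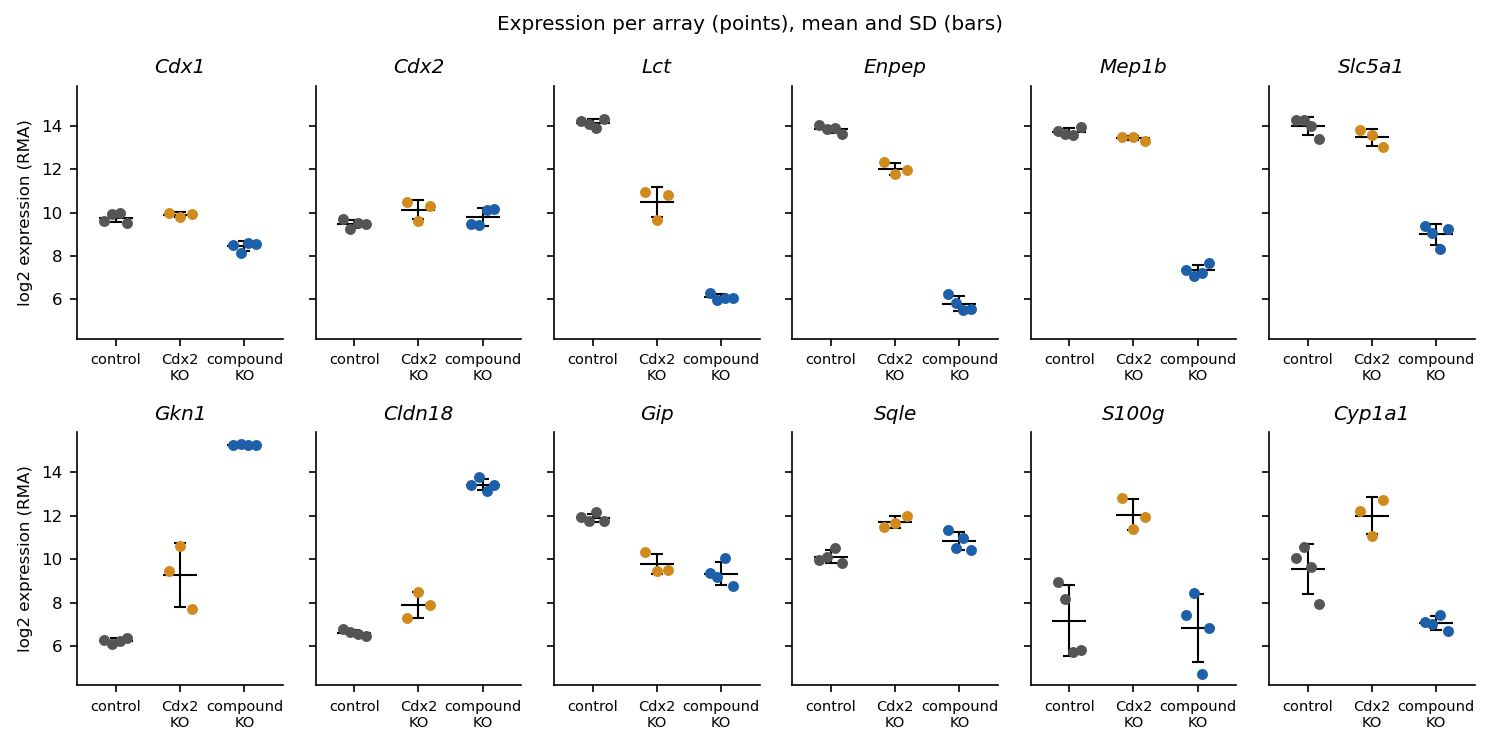
Log2 expression (RMA) of 12 genes on each array (points), with the mean and SD of each group (bars) for 4 control, 3 Cdx2 knockout and 4 compound knockout arrays. Lct steps down from 14.13 in controls to 10.49 and 6.11, Gkn1 steps up from 6.24 to 9.25 and 15.26, and S100g is highest in the Cdx2 knockout at 12.05.

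Several fixed gene lists moved on balance in the Cdx2 knockout. Of 26 measured brush border and digestion genes 10 fell and 0 rose (13 and 0 adjusted over the list alone), with Pdzk1, a scaffold protein, at -4.16 ± 0.41 and Lct as above (camera adjusted p = 2.47e-09). Of 23 enteroendocrine genes 14 fell and 0 rose (15 and 0 adjusted over the list alone; camera adjusted p = 1.64e-12), led by Nts, the peptide neurotensin, at -3.32 ± 0.47 and by Gip. Of 22 gastric and foregut genes 9 rose and 0 fell (12 and 0 adjusted over the list alone; camera adjusted p = 1.28e-09), with Anxa10 at 3.43 ± 0.42 and Gkn3. Of 22 cholesterol synthesis genes 14 rose and 0 fell (17 and 0 adjusted over the list alone; camera adjusted p = 3.45e-14), with Fdft1, squalene synthase, at 1.69 ± 0.28, Cyp51, and Sqle, squalene epoxidase, at 1.61 ± 0.23. With an estimated correlation these calls were lost, at adjusted p = 0.165 for brush border, adjusted p = 0.0533 for enteroendocrine, adjusted p = 0.111 for gastric and adjusted p = 0.132 for cholesterol synthesis genes (camera). Directional fry called these lists in the same directions, at adjusted p = 0.00041 for enteroendocrine and 0.00248 for each of the others.

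Of 24 genes of fatty acid oxidation and ketogenesis 7 rose and 1 fell (11 and 1 adjusted over the list alone; camera adjusted p = 0.000205; adjusted p = 0.582 with an estimated correlation). The largest changes in it were those of Pdk4 and of Angptl4, an inhibitor of lipoprotein lipase, at 4.60 ± 0.31, neither of them an enzyme of fatty acid oxidation. Of 25 xenobiotic metabolism genes 7 rose and 4 fell (10 and 4 adjusted over the list alone; camera adjusted p = 0.00155; adjusted p = 0.712 with an estimated correlation), with Gsta4, a glutathione transferase, at 4.30 ± 0.22 and Abcb1a at -4.54. Without Cdx2 knockout array 1 this call was lost (camera adjusted p = 0.0902). Of 22 interferon response genes 9 rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 0.00103; adjusted p = 0.712 with an estimated correlation), with Usp18 at 2.35 ± 0.22, whose values equal those of an unnamed entry, and Isg15 at 2.24 ± 0.33. Without Cdx2 knockout array 3, the array with the highest 18S signal, the interferon call was lost (camera adjusted p = 0.255).

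Of 21 mineral absorption genes 4 fell and 1 rose (5 and 2 adjusted over the list alone; camera adjusted p = 0.0155; adjusted p = 0.495 with an estimated correlation). Car4 and Vdr, the vitamin D receptor (-1.69 ± 0.18), fell while S100g rose, and the call was lost without Cdx2 knockout array 3 (camera adjusted p = 0.121). Of 15 tuft cell genes 2 rose (8 adjusted over the list alone; camera adjusted p = 1.59e-05; adjusted p = 0.582 with an estimated correlation). These were Avil, at 1.63 ± 0.37, and Alox5ap, at 1.63 ± 0.43, and both calls were lost without control array 3 (adjusted p = 0.0536 and 0.104), without control array 4 (0.0602 and 0.126), without Cdx2 knockout array 1 (0.0996 and 0.172) and without Cdx2 knockout array 2 (0.0947 and 0.186, limma). Alox5ap was also lost without control array 2 (adjusted p = 0.0662, limma) and with a replicate block (1.509, adjusted p = 0.132, limma). Of 30 cell cycle genes 1 fell and 0 rose (0 and 0 adjusted over the list alone), although the list was called lower (camera adjusted p = 5.37e-05; adjusted p = 0.712 with an estimated correlation). Without Cdx2 knockout array 2 this call was lost (camera adjusted p = 0.0524). Of 18 endoplasmic reticulum stress genes 0 passed the threshold (0 adjusted over the list alone, 7 at an unadjusted p under 0.05 by limma), and the list was called lower (camera adjusted p = 0.0116; adjusted p = 0.495 with an estimated correlation), a call lost without control array 2 (0.0762) or Cdx2 knockout array 2 (0.0524).

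Of 22 nutrient transport genes 6 fell and 3 rose (6 and 4 adjusted over the list alone; camera adjusted p = 0.0826), with Slc1a1, a glutamate transporter, at -2.17 ± 0.22. That list was called lower without control array 4 (camera adjusted p = 0.00736) or Cdx2 knockout array 1 (0.0168), with a replicate block (0.0179) and with a term for the sex pattern (0.0226). It was not called with an estimated correlation (camera adjusted p = 0.712). Of 28 lipid absorption genes 4 rose and 4 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.521), with Bco1, which cleaves beta-carotene, at 4.74 ± 0.67 and Scarb1, a lipoprotein receptor, at 3.40 ± 0.21. The median of that list was -0.13 and its mean 0.03. Isx, a homeobox repressor of Bco1 and Scarb1, fell by 3.02 ± 0.18 (adjusted p = 3.43e-06, limma with Benjamini-Hochberg), and 5 of 31 intestinal transcription factors rose and 3 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.46). No member passed the threshold among 15 goblet (camera adjusted p = 0.746), 10 Paneth (0.746), 17 T lymphocyte (0.789), 14 myeloid (0.667) or 25 Hox cluster genes (0.655). At an unadjusted p under 0.05 limma gave 0, 3, 1, 2 and 2 members of these 5 lists. Adjusted over the list alone, 1 Paneth gene rose, and 0 members of the other lists were called. Of 18 stroma and muscle markers 0 rose and 0 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.0572), and the list was called higher with a replicate block (camera adjusted p = 0.0102), without control array 4 (0.0232) or without Cdx2 knockout array 2 (0.0288), but not with an estimated correlation (0.582).

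The third comparison asked what differed in arrays labelled as compound knockout. Genes of the brush border and nutrient transport lists were nearly all lower in the 4 compound knockout arrays than in the 4 controls, and 16 of 22 gastric and foregut genes were higher. Lct fell by 8.02 ± 0.23 on the log2 scale (SE; adjusted p = 2.07e-09), and Enpep, the brush border aminopeptidase A, fell by 8.03 ± 0.17 (adjusted p = 2e-10, limma with Benjamini-Hochberg). Gkn1, a secreted protein of the gastric surface mucosa, rose by 9.02 ± 0.45 (adjusted p = 9.79e-08), and Cldn18, a claudin of stomach and lung, rose by 6.83 ± 0.22 (adjusted p = 3.43e-09, limma). Of 19637 entries 5877 passed the threshold (29.9%), 3281 higher and 2596 lower, and 7974 had an unadjusted p under 0.05. At least 2-fold changes were 769 up and 1055 down, and at least 4-fold changes 218 up and 390 down. The authors' deposited table lists 6910 of 22523 features at a false discovery rate under 0.05, of which 3898 were up and 3012 down.

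Other large rises among entries with a symbol and separate arrays were those of Anxa10, an annexin of the stomach, at 8.09 ± 0.39, Gkn2, a further gastrokine, at 7.62 ± 0.41, and Ly6d, at 6.69 ± 0.28. Plat, tissue plasminogen activator, rose by 6.64 ± 0.14, Mal, a protein of apical membrane sorting, by 6.50 ± 0.14, and Sptssb, a subunit of serine palmitoyltransferase, by 6.36 ± 0.44. After Enpep and Lct, the largest falls were those of 2010106E10Rik, at -7.75 ± 0.60, Clca4b, at -6.73 ± 0.31, and Dnase1, at -6.40 ± 0.17. They were followed by Mep1b, a subunit of the metalloprotease meprin, at -6.38 ± 0.13, Cyp4f14, a cytochrome P450, at -6.36 ± 0.25, and Pmp22, a membrane protein, at -6.31 ± 0.31. Adjusted p of these genes was at most 2.95e-06, for 2010106E10Rik (limma with Benjamini-Hochberg). Mep1b read 13.72 ± 0.18 (SD, n = 4) in controls, 13.42 ± 0.09 (n = 3) in Cdx2 knockouts and 7.34 ± 0.26 (n = 4) in compound knockouts.

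Lists of absorptive function were lower, and the gastric list was higher. Of 26 brush border and digestion genes 23 fell and 1 rose (23 and 1 adjusted over the list alone; camera adjusted p = 1.93e-23), among them Treh, trehalase, at -5.93 ± 0.33. Of 22 nutrient transport genes 20 fell and 1 rose (20 and 1 adjusted over the list alone; camera adjusted p = 6.04e-19), among them Cubn and Amn, which together form the receptor for intrinsic factor with cobalamin, at -6.20 ± 0.41 and -5.32 ± 0.18, and Slc5a1, the apical glucose transporter, at -4.97 ± 0.27. Of 22 gastric and foregut genes 16 rose and 0 fell (16 and 0 adjusted over the list alone; camera adjusted p = 4.15e-12). These 3 calls held with an estimated correlation, at adjusted p = 0.0341 for brush border, adjusted p = 0.0341 for transport and adjusted p = 0.0408 for gastric genes (camera). Of 28 lipid absorption genes 23 fell and 3 rose (23 and 3 adjusted over the list alone; camera adjusted p = 1.03e-13; adjusted p = 0.0716 with an estimated correlation), among them Apoc3, an apolipoprotein, at -4.26 ± 0.23 and Mttp, which loads lipid onto apolipoprotein B, at -2.93 ± 0.12. Of 21 mineral absorption genes 11 fell and 1 rose (11 and 1 adjusted over the list alone; camera adjusted p = 1.1e-06; adjusted p = 0.0611 with an estimated correlation), among them Car4 at -5.97 and Heph, the iron oxidase hephaestin, at -5.0 ± 0.22.

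Of 30 cell cycle genes 26 fell and 0 rose (28 and 0 adjusted over the list alone; camera adjusted p = 4.15e-12; adjusted p = 0.461 with an estimated correlation), among them Top2a, a topoisomerase of dividing cells, at -2.73 ± 0.44 and Birc5, survivin, at -2.65 ± 0.41. The list mean of single control arrays ranged from -0.79 to 0.87 around the control mean, and that of compound arrays from -1.72 to -1.23. Of 23 enteroendocrine genes 13 fell and 0 rose (14 and 0 adjusted over the list alone; camera adjusted p = 5.46e-07; adjusted p = 0.0676 with an estimated correlation), with Nts at -3.73 ± 0.43 and Gip at -2.57 ± 0.26. Of 15 tuft cell genes 10 rose and 0 fell (11 and 0 adjusted over the list alone; camera adjusted p = 0.00199; adjusted p = 0.586 with an estimated correlation), with Avil at 2.23 ± 0.34 and Alox5ap at 2.16 ± 0.40. With a term for the sex pattern the tuft call was lost (camera adjusted p = 0.0505). Of 21 oxidative phosphorylation genes 11 fell and 0 rose (13 and 0 adjusted over the list alone; camera adjusted p = 5.93e-06; adjusted p = 0.461 with an estimated correlation), with Ppargc1a, a transcriptional coactivator rather than a subunit, at -1.93 ± 0.29 and Sdha, a subunit of succinate dehydrogenase, at -0.68 ± 0.08. Of 18 endoplasmic reticulum stress genes 9 fell and 2 rose (10 and 2 adjusted over the list alone; camera adjusted p = 0.00125; adjusted p = 0.196 with an estimated correlation), with Ddit3, a transcription factor of that response, at -1.16 ± 0.17 and Herpud1 at 1.40.

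Of 22 interferon response genes 13 fell and 0 rose (14 and 0 adjusted over the list alone; camera adjusted p = 5.36e-05; adjusted p = 0.517 with an estimated correlation). Among the falls were those of H2-Aa (-3.74 ± 0.91), Cd74 (-3.55 ± 0.91) and H2-Eb1 (-3.11 ± 0.72), which serve antigen presentation by major histocompatibility complex class II. Their single calls were lost with a term for the sex pattern, at adjusted p = 0.0913 for H2-Aa, adjusted p = 0.13 for Cd74 and adjusted p = 0.0862 for H2-Eb1 (limma). Of 25 xenobiotic metabolism genes 12 fell and 6 rose (13 and 6 adjusted over the list alone; camera adjusted p = 0.00638; adjusted p = 0.627 with an estimated correlation), with Adh6a, an alcohol dehydrogenase, at -6.26 ± 0.25 and Gsta4 at 4.93 ± 0.20. Of 17 T lymphocyte markers 7 fell and 0 rose (7 and 0 adjusted over the list alone; camera adjusted p = 0.00352; adjusted p = 0.586 with an estimated correlation), with the granzymes Gzma at -2.57 ± 0.56 and Gzmb at -2.35 ± 0.42. The list mean of T lymphocyte markers was -0.91, -0.75, -0.12 and -0.75 in compound arrays 1 to 4.

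The other lists were not called in the compound knockout, although single members moved. Of 9 ileal bile acid genes 3 rose and 2 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.496), with Slc51a, a subunit of the basolateral bile acid transporter, at -4.69 ± 0.27. Of 24 genes of fatty acid oxidation and ketogenesis 10 rose and 4 fell (10 and 5 adjusted over the list alone; camera adjusted p = 0.276), with Pdk4 at 5.86 ± 0.67. Of 22 cholesterol synthesis genes 4 rose and 6 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.442), with Dhcr7, the last enzyme of that pathway, at -1.81 ± 0.15, and the list median was 0.05 against a mean of -0.09. Of 31 intestinal transcription factors 10 rose and 12 fell (11 and 12 adjusted over the list alone; camera adjusted p = 0.306), with Hnf4g, a nuclear receptor, at -3.69 ± 0.35 and Isx at -3.40 ± 0.16. Of 23 junction and adhesion genes 7 rose and 7 fell (7 and 7 adjusted over the list alone; camera adjusted p = 0.21), with Cdh17, an intestinal cadherin, at -4.80 ± 0.17 and Cldn15 at -3.72 ± 0.14, and the list also holds Heph, which is not a junction protein. With a term for the sex pattern that list was called lower (camera adjusted p = 0.0216), but not with an estimated correlation (0.641). Of 25 inflammation and antimicrobial genes 3 rose and 6 fell (3 and 6 adjusted over the list alone; camera adjusted p = 0.0619), with Ccl25, a chemokine that draws lymphocytes to the small intestine, at -5.52 ± 0.14 and Reg3a at -5.05 ± 0.23. That list was called lower without control array 1 (camera adjusted p = 0.0474) or control array 3 (0.0418), but not with an estimated correlation (0.641). Of 15 goblet cell genes 6 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.442), with Agr2 at -2.83 ± 0.30, a list whose median was 0.44 and mean -0.10. Of 14 colon genes 2 rose and 4 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.306), with Car2, a cytosolic carbonic anhydrase, at 5.66 ± 0.31 and Slc26a3, a chloride and bicarbonate exchanger, at -3.43 ± 0.29.

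Crypt and stem cell genes, 20 measured, rose in 3 cases and fell in 3 (camera adjusted p = 0.841), and of 10 Paneth cell genes 2 rose and 2 fell (0.496), with Ang4, an antimicrobial ribonuclease, at -2.96 ± 0.36. Of 9 squamous and oesophageal genes 1 rose (camera adjusted p = 0.841), and of 25 Hox cluster genes 1 fell and 24 were not called (0.925). Of 14 myeloid markers 3 fell (camera adjusted p = 0.305), with Ctss, the protease cathepsin S, at -2.73 ± 0.23. Of 14 exocrine pancreas genes 3 rose and 1 fell (camera adjusted p = 0.305), with Ctrb1, chymotrypsinogen, at 1.91. There was 1 call each, upward, among 10 B and plasma cell markers (camera adjusted p = 0.943), 18 stroma and muscle markers (0.496), 10 endothelial markers (0.306) and 4 erythroid markers (0.496). In the sex check list of 5 genes, Xist rose by 3.0 ± 1.04 (adjusted p = 0.0497) and Ddx3y, a Y-linked helicase, fell by 2.15 ± 0.70 (adjusted p = 0.0389, limma), and the list was not called (camera adjusted p = 0.22), except as lower without the 2 arrays with raised 18S (0.0487). Leaving out any control array, or any of compound arrays 1 to 3, ended both calls, at adjusted p = 0.0757 to 0.121 for Xist and adjusted p = 0.0612 to 0.095 for Ddx3y (limma).

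**Figure D2:**
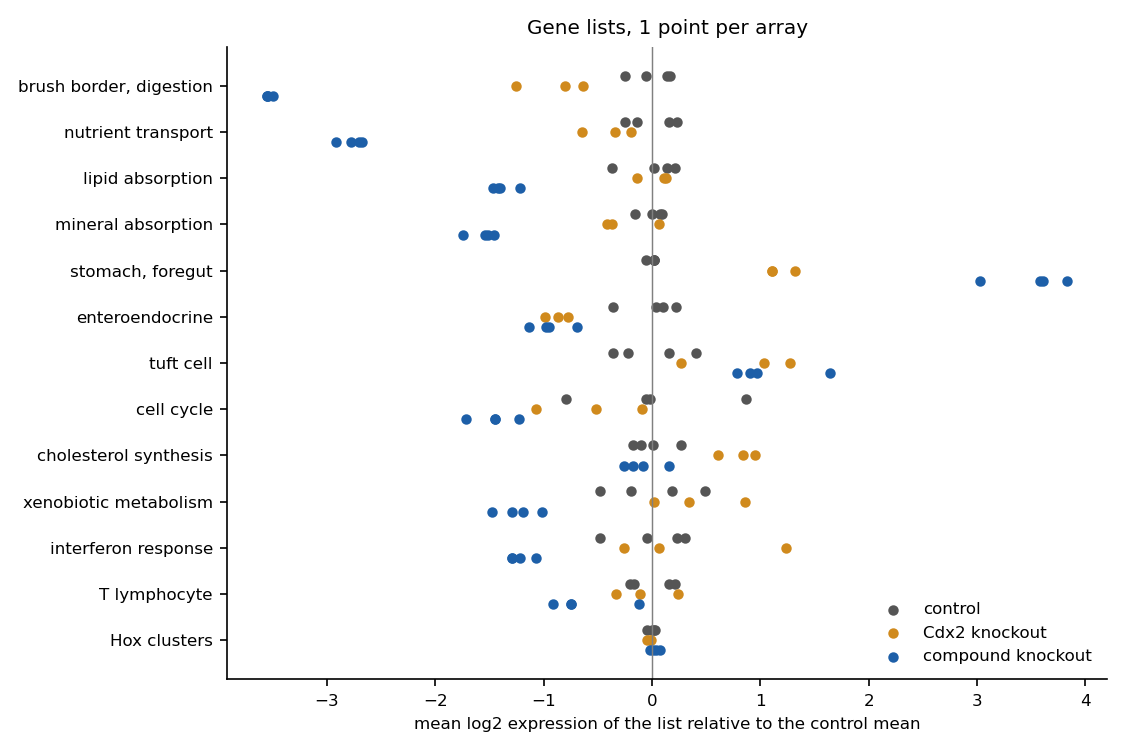
Mean log2 expression of 13 gene lists relative to the control mean (horizontal axis), with 1 point per array for 4 control, 3 Cdx2 knockout and 4 compound knockout arrays. The brush border list averages -0.90 in the Cdx2 knockout and -3.54 in the compound knockout, and the stomach and foregut list 1.18 and 3.51.

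The fourth comparison asked what differed between the 2 labelled knockouts, by setting the 4 compound arrays against the 3 Cdx2 knockout arrays. No arrays of a Cdx1 knockout alone were among the samples. An effect of Cdx1 loss alone therefore cannot be told from a joint effect of losing both factors. Most genes of the brush border and nutrient transport lists were lower in the compound arrays than in the Cdx2 knockout arrays, and 14 of 22 gastric genes were higher. Mep1b fell by 6.09 ± 0.14 on the log2 scale (SE; adjusted p = 1.22e-09), and Slc2a2, the basolateral glucose transporter, fell by 4.63 ± 0.31 (adjusted p = 2.76e-06, limma with Benjamini-Hochberg). Mal rose by 6.26 ± 0.15 and Plat by 6.17 ± 0.15 (adjusted p = 1.22e-09 for each, limma). Of 19637 entries 3882 passed the threshold (19.8%), 2234 higher and 1648 lower, and 6740 had an unadjusted p under 0.05. Without Cdx2 knockout array 1 the count was 2585, with 1337 higher, and without array 3 the number higher was 1416. On a single simulated data set per contrast, with 200 changed genes, the false share of calls was 10.81% here, above the nominal 5%, against 4.92% and 5.8% in the other contrasts. From a single draw each, these shares cannot tell whether this contrast differs from the others.

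Further large rises were those of Gkn1 (6.01 ± 0.49), Cldn18 (5.54 ± 0.24), Psca, prostate stem cell antigen, which the stomach also expresses (4.88 ± 0.28), Gkn2 (4.68 ± 0.44), Anxa10 (4.66 ± 0.42) and Gsdma2, a gasdermin (4.65 ± 0.44). Further large falls were those of Enpep (-6.21 ± 0.19), Enpp3, an ectonucleotidase (-6.06 ± 0.41), Cyp4f14 (-6.0 ± 0.27), Clca4b (-5.61 ± 0.34), Abhd3, a phospholipase (-5.56 ± 0.31), S100g (-5.20 ± 0.94) and Alpi, intestinal alkaline phosphatase (-5.19 ± 0.58). Of these genes, S100g had the highest adjusted p, 0.00274 (limma with Benjamini-Hochberg). Of 26 brush border genes 20 fell and 0 rose (22 and 0 adjusted over the list alone; camera adjusted p = 2.93e-25), of 22 transport genes 18 fell and 0 rose (18 and 0 adjusted over the list alone; 6.91e-21), of 28 lipid absorption genes 21 fell and 0 rose (22 and 1 adjusted over the list alone; 1.3e-18), and of 22 gastric genes 14 rose and 0 fell (15 and 0 adjusted over the list alone; 1.25e-10). These 4 calls held with an estimated correlation, at adjusted p = 0.0253 for brush border, adjusted p = 0.0253 for transport, adjusted p = 0.0484 for lipid absorption and adjusted p = 0.0484 for gastric genes (camera). Of 21 mineral absorption genes 9 fell and 1 rose (10 and 1 adjusted over the list alone; camera adjusted p = 2.48e-06; adjusted p = 0.06 with an estimated correlation). The enteroendocrine list had 1 member higher and 1 lower between the knockouts (camera adjusted p = 0.748).

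The cholesterol synthesis, interferon and xenobiotic lists were lower in the compound knockout than in the Cdx2 knockout, with the preset correlation. Against control, the Cdx2 knockout calls of these lists had been upward with the preset correlation and were lost with an estimated one, at adjusted p = 0.132, 0.712 and 0.712 (camera). Without Cdx2 knockout array 3 the mean change of the interferon list against control was -0.10. Of 22 cholesterol synthesis genes 16 fell and 1 rose (20 and 1 adjusted over the list alone; camera adjusted p = 3.71e-12; adjusted p = 0.107 with an estimated correlation), with Dhcr7 at -2.13 ± 0.17 and Nsdhl, a sterol dehydrogenase, at -1.40 ± 0.15. Of 22 interferon response genes 13 fell and 0 rose (15 and 0 adjusted over the list alone; camera adjusted p = 5.3e-12; adjusted p = 0.156 with an estimated correlation), with Ifit1 at -4.14 ± 0.38 and Isg15 at -3.19 ± 0.33. Of 25 xenobiotic genes 12 fell and 0 rose (13 and 1 adjusted over the list alone; camera adjusted p = 5.13e-09; adjusted p = 0.218 with an estimated correlation), with Adh6a at -4.98 and Cyp1a1, a cytochrome P450 induced by aryl hydrocarbons, at -4.95 ± 0.55. Cyp1a1 read 9.55 in controls, 12.00 in Cdx2 knockouts and 7.05 in compound knockouts, and S100g read 7.16, 12.05 and 6.85. Both genes are among 182 entries that rose in the Cdx2 knockout and fell between the knockouts, of which 42 ended below control and 120 were not called against control. The rise of Cyp1a1 in the Cdx2 knockout (2.46 ± 0.55, adjusted p = 0.0216) was lost without Cdx2 knockout array 1 (0.0746) or array 3 (0.0893, limma). In the converse direction there were 43 entries.

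Of 30 cell cycle genes 8 fell and 0 rose between the knockouts (10 and 0 adjusted over the list alone; camera adjusted p = 2.58e-08; adjusted p = 0.449 with an estimated correlation). The largest of these, Mcm6 (-1.91 ± 0.45) and Birc5 (-1.88 ± 0.45), lost their calls without Cdx2 knockout array 1 (adjusted p = 0.0601 and 0.051) or array 3 (0.0521 and 0.055, limma). Of 21 oxidative phosphorylation genes 7 fell and 0 rose (8 and 0 adjusted over the list alone; camera adjusted p = 0.000203; adjusted p = 0.446 with an estimated correlation), with Sdha at -0.71 ± 0.08. Of 17 T lymphocyte markers 3 fell and 0 rose (2 and 0 adjusted over the list alone; camera adjusted p = 0.0021; adjusted p = 0.449 with an estimated correlation). Of 9 ileal bile acid genes 4 fell and 0 rose (5 and 0 adjusted over the list alone; camera adjusted p = 0.0363; adjusted p = 0.446 with an estimated correlation), with Slc51a at -2.83 ± 0.29. Without Cdx2 knockout array 1 (0.061) or compound array 4 (0.0593) that list's call was lost (camera).

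The next comparison asked how far the change in the compound knockout was already present in the Cdx2 knockout. Across 1824 genes with at least a 2-fold change in the compound knockout, the median share of the log2 change seen in the Cdx2 knockout was 35.5%, against 27% to 34.1% with the 4 shared controls split 2 against 2, and 1.3% (0.4% to 1.9%) in 100 simulations with an unchanged Cdx2 knockout. Of 1055 such falls 338 were also called as falls in the Cdx2 knockout, and of 769 such rises 303 were also called as rises. With split controls, which leave fewer arrays per fit, these shared calls were 65 to 239 and 61 to 165, and in the simulations at most 1 and 1. Genes that fell in both knockouts numbered 540, or 90.8% of the falls in the Cdx2 knockout, and genes that rose in both 468, or 70.7%. Independent lists would share 79 and 111. Because both comparisons used the same 4 controls, the split was also made for all calls, which gave overlaps of 70 to 308 for falls and 68 to 189 for rises over 6 splits. Each split fit used 2 controls and made its own lists, so 79 and 111 are not its reference. An expected overlap for the split lists was not computed. The Pearson correlation of log2 changes across genes was 0.655, against 0.465 in 100 simulations of unchanged groups with shared controls (0.429 to 0.506), and 0.514 to 0.623 with split controls. The share of genes with the same sign was 63.05%, against 65.31% in the simulations (64.28% to 66.32%) and 51.98% to 62.15% with split controls. All these simulations drew genes independently of each other, while real genes can vary together across arrays. Their ranges can therefore be too narrow.

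**Figure D3:**
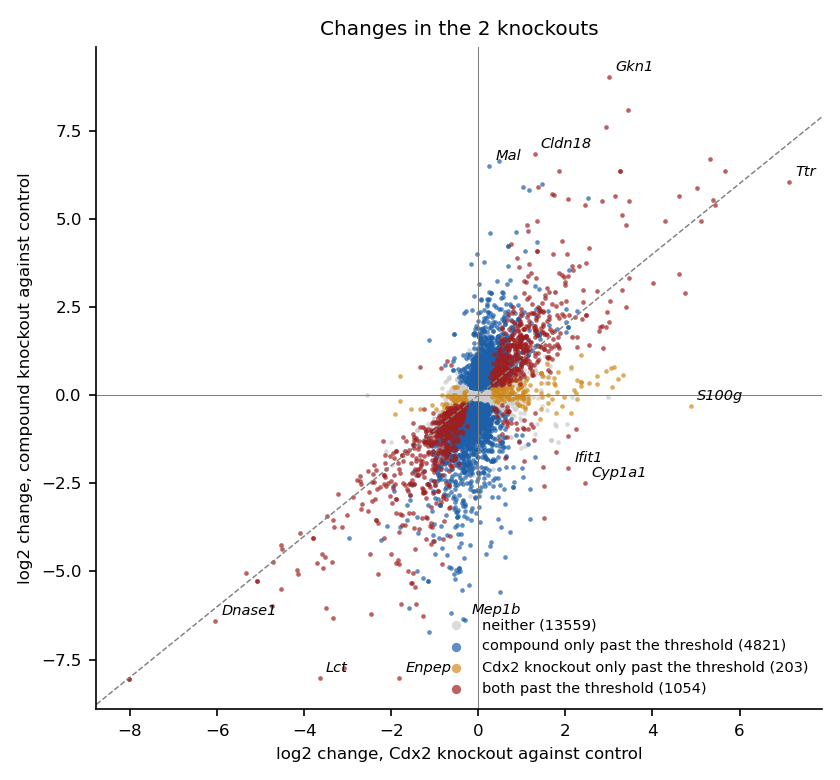
Log2 change in the Cdx2 knockout (horizontal axis) against log2 change in the compound knockout (vertical axis), both against the same 4 controls, with 1 point per entry and a dashed line of equal change. Past the threshold in both comparisons were 1054 entries, in the compound knockout alone 4821 and in the Cdx2 knockout alone 203, and S100g and Cyp1a1 lie to the right of the line.

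The ChIP-seq comparison asked where Cdx2 bound in villus cells. The authors' list holds 8775 peaks on mouse build mm9, with a median width of 559 bp (212 to 3539), and covers 5.37 Mb. The fold enrichment and the score of a peak are the authors' own values. The median fold was 14.25 (3.8 to 117.6) and the highest false discovery rate 12.23%. Reads in peaks made up 2.82% of the ChIP library (95% Wilson interval 2.81 to 2.84) and 0.428% of the input library (0.423 to 0.433), a ratio of 6.59 after scaling to the size of each library (95% interval 6.50 to 6.67). These intervals cover counting error only. The peaks were called on these same 2 libraries, so a ratio above 1 follows from the calling. Among the 1000 peaks of highest significance, the highest fold enrichment, 117.58, belonged to the peak on chromosome 2 at 37478649 to 37479272, with 45 tags. The next 4 lay on chromosome 6 at 22208487 to 22209221 (fold 111.92), chromosome 5 at 29538320 to 29539340 (109.38), chromosome 15 at 58611173 to 58611891 (95.03) and chromosome 6 at 149405745 to 149406535 (87.11). Ranks 6 to 10 were on chromosome 3 at 88192000 to 88192307 (84.77), chromosome 12 at 106129124 to 106129969 (83.36), chromosome 1 at 108483142 to 108484141 (80.35), chromosome 8 at 8682621 to 8683106 (79.7) and chromosome 8 at 94419880 to 94420513 (79.3). Gene annotation at these positions was not used here.

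**Figure D4:**
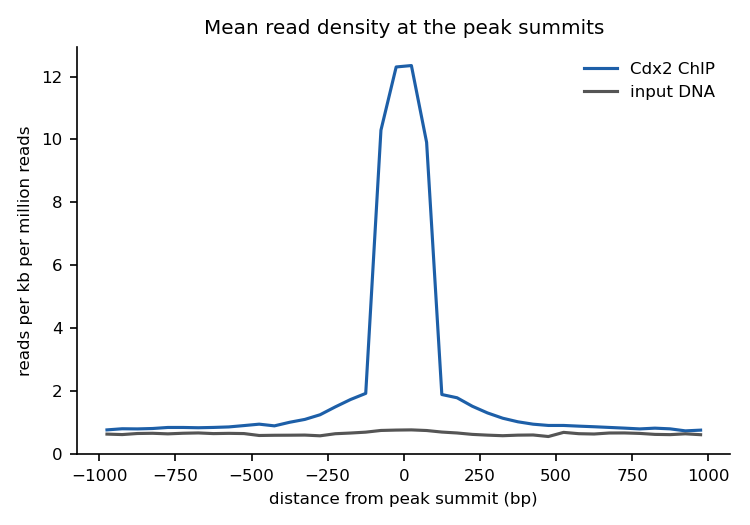
Mean read density (reads per kb, scaled to library size as the axis states) of the Cdx2 ChIP and input DNA libraries against distance from the peak summit in bp, with reads shifted by 90 bp toward the fragment centre. The ChIP library reaches 12.35 at the summit against 0.79 beyond 800 bp, and the peaks were called on these same reads.

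The last comparison asked whether genes that changed lay near Cdx2 peaks, by the authors' assignment of peaks within 20 kb of the transcription start. Genes that fell had peaks more often than genes that were not called, and some gene lists had them more often than all genes. Of 2275 genes that fell in the compound knockout 828 had a peak (36.4%), against 17.2% of 10804 genes not called (odds ratio 2.76, 95% interval 2.50 to 3.05, two-sided Fisher's exact test, p = 4.08e-85). In the Cdx2 knockout 236 of 512 fallen genes had a peak (46.1% against 18.9%; odds ratio 3.66, 3.05 to 4.39, Fisher's exact p = 1.69e-42), and between the knockouts 540 of 1439 (37.5% against 18.5%; odds ratio 2.65, p = 1.82e-56). Genes with peaks were more highly expressed, and within quintiles of mean level the odds ratios for falls were 2.04 (1.83 to 2.26) in the compound knockout, 2.96 (2.47 to 3.56) in the Cdx2 knockout and 1.81 (1.60 to 2.05) between them (Mantel-Haenszel). Genes that rose in the compound knockout had a peak in 18.3% of cases (odds ratio 1.08, Fisher's exact p = 0.158; 0.884 within quintiles, Mantel-Haenszel p = 0.035). That odds ratio passed the threshold without control array 1 (1.166, Fisher's exact p = 0.00848), control array 2 (1.168, p = 0.00989), compound array 2 (1.12, p = 0.0482) or compound array 4 (1.165, p = 0.00868). For rises in the Cdx2 knockout the odds ratio was 1.59 (1.32 to 1.92, Fisher's exact p = 1.72e-06), and 1.11 within quintiles (Mantel-Haenszel p = 0.315). Genes are the units of these tests and are not independent replicates. The median log2 change of 3183 genes with a peak differed from that of 12633 genes without by -0.078 in the compound knockout (camera p = 0.000635; p = 0.00239 with an estimated correlation), -0.058 between the knockouts (p = 0.0027) and -0.03 in the Cdx2 knockout (p = 0.0679). This last shift passed the camera threshold without control array 3 (-0.034), control array 4 (-0.031) or Cdx2 knockout array 1 (-0.036), and with a replicate block (-0.032). Medians with and without a peak were -0.017 and 0.061 in the compound knockout and 0.003 and 0.062 between the knockouts. Much of the difference in these contrasts thus lay in genes without a peak, whose median was above 0. In the Cdx2 knockout the medians were -0.034 and -0.004. These shifts were not adjusted for level.

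Of the 8 largest falls with a peak in the compound knockout, the nearest peak lay at 46 bp from the transcription start for Lct, which had 4 peaks within 20 kb, 53 bp for Adh6a and 221 bp for Dnase1. It lay at 1404 bp for Cubn, also with 4 peaks, 2201 bp for Cyp4f14, 8375 bp for Pmp22, 10141 bp for Enpep and 10710 bp for 2010106E10Rik. The 4 largest rises with a peak were those of Psca (5.90 ± 0.26), Tff2, a trefoil peptide of the stomach (5.66 ± 0.23), Lyve1 (5.38 ± 0.28) and Pllp, plasmolipin (4.16 ± 0.13), with peaks at 2243, 9140, 2822 and 6551 bp. In the compound knockout 30.7% of 538 genes with a peak within 1 kb fell (exact interval 26.8 to 34.8), and 9.0% of 6650 genes with no peak within 100 kb did (8.3 to 9.7). By the number of peaks within 20 kb, 11.5% of genes with 0 peaks fell, 23.7% with 1, 33.7% with 2, 36.8% with 3 and 42.3% of 52 genes with at least 4. These shares by distance and number were not adjusted for level, whose median went from 8.76 within 1 kb to 7.05 beyond 100 kb. Among genes without a peak 2.1% fell in the lowest quintile of level and 23.9% in the highest, against 4.3% and 38.8% of genes with a peak. Against 20.1% of all genes, a peak was present for 19 of 31 intestinal transcription factors (61.3%, Fisher's exact adjusted p = 1.02e-05), 15 of 23 junction genes (65.2%, 2.62e-05), 17 of 28 lipid absorption genes (60.7%, 2.62e-05), 15 of 26 brush border genes (57.7%, 0.000177), 14 of 25 xenobiotic genes (56%, 0.000431) and 12 of 22 transport genes (54.5%, 0.00168). Hox cluster genes had one in 19 of 25 cases (76%, 9.06e-08), but neighbours in a cluster can share a peak. The shares of these lists were not adjusted for level, and in the highest quintile of level 32.7% of genes had a peak. Not past the threshold were mineral absorption, with 8 of 21 (38.1%, Fisher's exact adjusted p = 0.171), and ileal bile acid genes, with 5 of 9 (55.6%, adjusted p = 0.0804). Among gastric genes 5 of 22 had one (22.7%, adjusted p = 0.972), and among enteroendocrine genes 4 of 23 (17.4%, adjusted p = 1).

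**Figure D5:**
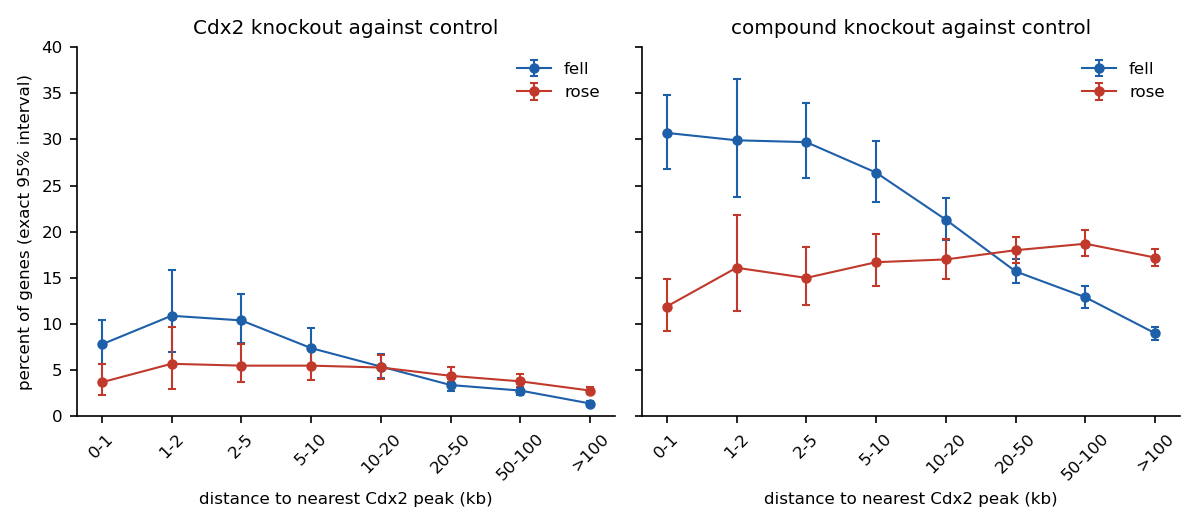
Percent of genes that fell or rose (vertical axis, exact 95% intervals) by distance in kb from the transcription start to the nearest Cdx2 peak, for the Cdx2 knockout and the compound knockout against control. In the compound knockout the share that fell goes from 30.7% within 1 kb to 9.0% beyond 100 kb, while the share that rose goes from 11.9% to 17.2%. The median level goes from 8.76 to 7.05 over the same distances, and the shares are not adjusted for it.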

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

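The tests of the cholesterol synthesis and interferon lists, the share of the log2 change kept under other settings, and the limit to splits that part all pairs, were chosen only after the result was seen. In groups of 4 arrays, the highest or lowest array was compared with the nearest other by Dixon's gap, for the 95 genes named in the text and for the 32 lists. It passed the bound in 11 of 190 gene and group pairs and in 4 of 64 list and group pairs, together 5.9%, where chance gives about 1 in 20 groups. Among controls, array 1 stood apart for Tmigd1 at 10.71 (others 9.16 to 9.36), array 3 for Gml2 at 5.92 (5.46 to 5.51) and Gsta4 at 8.79 (9.62 to 9.74), and array 4 for Ifit1 at 10.82 (9.24 to 9.49), Psca at 7.19 (7.5 to 7.55) and Slc2a2 at 11.58 (12.23 to 12.33). Compound array 3 stood apart for Gsdma2 at 10.49 (12.42 to 12.67) and Gzma at 9.72 (7.01 to 7.32), and compound array 4 for Slc51a at 7.18 (7.85 to 7.99), Ddx3y at 8.34 (5.57 to 5.97) and Xist at 6.31 (10.12 to 10.60). List means stood apart for ileal bile acid genes in control array 1 at 0.79 (-0.33 to -0.15), gastric genes in control array 3 at -0.06 (0.02), fatty acid oxidation genes in compound array 3 at 1.19 (0.71 to 0.74) and endothelial markers in control array 4 at 0.16 (-0.07 to -0.04).

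Signals outside the comparisons lay above all controls on several arrays. The 18S features read 10.32 in Cdx2 knockout array 3 and 9.07 in compound array 4, against at most 7.88 in controls. Xist read 10.45 in Cdx2 knockout array 1 and 10.47, 10.12 and 10.60 in compound arrays 1 to 3, against at most 6.66 in controls. Tests of the difference between the knockouts found 182 entries that rose in the Cdx2 knockout and then fell, and 43 that fell and then rose. The xenobiotic list (0.41 in the Cdx2 knockout, -1.25 in the compound knockout) differed by -1.65 between the knockouts, and the interferon list (0.34 and -1.22) by -1.56. The xenobiotic mean was 0.86, 0.34 and 0.02 in Cdx2 knockout arrays 1 to 3, against -0.48 to 0.49 in single controls, so its rise rested most on array 1.

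The number of changed genes was weighed against chance, sex and array quality. In both contrasts of the compound knockout only the real split, 1 of 35, gave as many genes, with 5488 and 3598 in 2-group fits against at most 1 and 5 in the others. An arbitrary split of these arrays thus did not give such counts. The other splits mix the labelled groups, which widens the spread within them, and arrays of a group may not be separate animals. Chance differences between animals are therefore not excluded. For the Cdx2 knockout (974 genes) the 8 splits that part all 3 pairs of arrays are too few for a share under 0.05, with at most 0 genes in the others of them and at most 0 in the 27 splits that keep a pair together. For the compound knockout, the count with a term for the sex pattern was 68.2% of the count without it, only just above the bound. That bound was set before this test was run but after the sex and 18S patterns had been seen. With the sex term 3718 of 5877 calls were made again in the same direction. Without the 2 arrays with raised 18S the count was 85.1% of the count with them, with 4818 calls made again. Over the 5877 called entries the median share of the log2 change kept was 101.2% with the sex term and 97.8% on arrays with Y-linked signal, with 1 change of sign in each. The latter value rests on compound array 4 alone, which is also the compound array with raised 18S. Without the 2 arrays with raised 18S the share kept was 100.7%, but compound arrays 1 to 3 all had high Xist. Sex alone or 18S alone therefore does not account for the changes as a whole, while no check removed both. With 1 compound array carrying Y-linked signal, sex remains an open explanation for single genes, and differences between animals were not tested.

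Entries that rose in the Cdx2 knockout and fell again in the compound knockout were weighed against noise of the shared Cdx2 knockout arrays. Among genes picked without 1 Cdx2 knockout array, that array lay above both other group means for 89.4%, 95.1% and 91.4%, against 18.8% to 25.5% of other genes. Noise of the Cdx2 knockout arrays used for picking would not carry over to the array left out. The control and compound arrays both picked the genes and set the means. The other genes are therefore not an even reference, and noise of the control and compound arrays was not tested. The mean rise of the cholesterol synthesis list kept 90.6% of its size without the 2 arrays with raised 18S and 100.6% with a sex term, so neither explains the whole of it, and no biological explanation was tested. For the interferon list, the mean change without Cdx2 knockout array 3 was -29.3% of the value with it, so the rise of the list as a whole rested on that array. In a fit without that array that stands apart, 6 of the 22 members were called higher and 2 lower (limma), so for single members the rise did not rest on array 3 alone.

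The excess of Cdx2 peaks among genes that fell in the compound knockout was weighed against expression level, since highly expressed genes could be easier to call. Within quintiles of mean level the odds ratio was 2.035 (1.83 to 2.26), against 2.76 without them. Level as split into these quintiles therefore accounts for part of the excess and not for the whole of it. How far level within a quintile or the single ChIP library shaped the rest remains open, and no biological explanation was tested.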

How the results depend on the processing

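Added after seeing the data were the sex term, arrays with Y-linked signal alone, leaving out the 2 arrays with raised 18S, identical values counted once, and peaks at any transcript. Genes changed in the Cdx2 knockout numbered 532 (295 up, 237 down) at 2-fold or more, 675 (347, 328) at adjusted p under 0.01, 608 (335, 273) on arrays with Y-linked signal and 826 (363 down) without raised 18S. In the compound knockout they numbered 1824 (769, 1055) at 2-fold, 3749 (1968 up) at 0.01 and 2194 (1253, 941) on arrays with Y-linked signal. Between the knockouts they numbered 1085 (373, 712), 1956 (958, 998), 780 (382, 398) and 2286 (1123 up) under these 4 settings. Stricter thresholds and fewer arrays give fewer calls by construction. Leaving out 1 array gave 863 to 1239, 4753 to 5709 and 2585 to 3790 genes, with 1337 to 2245 rises between the knockouts.

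With the replicate number as a block (replicate block), 977 of 1257, 5433 of 5877 and 3048 of 3882 calls were made again in the same direction, and 0 changed sign. Residual correlation of arrays sharing a number averaged 0.072 against -0.025 for other pairs, and 5 of 11 arrays matched their own number best, a hint from the data and not from the design. Apart from the calls given with a block in the report, the block changed no other call that the report names for the Cdx2 knockout against control, while for the other 2 contrasts the arrays share only a number. With an estimated correlation camera called 0, 3 and 4 lists in the 3 contrasts (11, 13 and 12 at the preset correlation). Directional fry called 6 lists in the Cdx2 knockout, namely brush border, mineral absorption, enteroendocrine, gastric, colon and cholesterol synthesis. It did not call the tuft, cell cycle, xenobiotic, fatty acid oxidation, endoplasmic reticulum stress and interferon lists, which camera had called at the preset correlation. Fry for changes either way called 21, 28 and 22 lists in the 3 contrasts. Xist reversed in the compound knockout, to -0.046 with the sex term and -0.064 on arrays with Y-linked signal, because these settings remove that difference. Of 5923 values for genes named by the rule, 5388 kept direction and call, 522 lost the call, 11 gained it and 2 reversed.

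The odds ratio of a peak among genes that fell stayed above 1 and past the threshold in all settings run, at 2.671 to 5.615, 2.127 to 3.814 and 1.932 to 3.458. Among genes that rose in the Cdx2 knockout it lost its call for peaks within 1 kb (1.036), within 2 kb (1.221) and at or above the median level (1.208). In the compound knockout it gained one within 50 kb (1.104) and without raised 18S (1.148), reversed at or above the median level (0.872, Fisher's exact p = 0.0356), and spanned 1.076 to 1.168 leaving out 1 array. Between the knockouts it gained a call within 1 kb (0.657), within 5 kb (0.813), at or above the median level (0.751) and with the sex term (0.834), and spanned 0.88 to 1.002 leaving out 1 array. The shift of genes with peaks in the Cdx2 knockout gained a call with an estimated correlation (-0.03), at or above the median level (-0.054), with the replicate block (-0.032) and with the sex term (-0.033), and spanned -0.036 to -0.024 leaving out 1 array. For these odds ratios and shifts the cause was not tested. There were 1976 peaks at a score of at least 100 and 5658 at a false discovery rate of at most 5%, with 1.039% and 2.093% of ChIP reads and ratios to input of 8.34 and 7.14, since these keep fewer and stronger peaks. Keeping 1 read per position gave 2.8% of ChIP reads.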

Other observations

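Hox cluster genes were close to Cdx2 peaks and mostly not called. Of 25 measured Hox genes 19 had a peak within 20 kb (76%, against 20.1% of all genes, Fisher's exact adjusted p = 9.06e-08), while 0 were called in the Cdx2 knockout, 1 in the compound knockout and 2 between the knockouts (limma; 2, 2 and 6 at an unadjusted p under 0.05). The list mean was -0.03 ± 0.02 (SD, n = 3) in the Cdx2 knockout and 0.02 ± 0.04 (n = 4) in the compound knockout, relative to control. Both Cdx genes had 2 peaks within 20 kb of their own transcription starts, the nearest at 3569 bp for Cdx1 and 2175 bp for Cdx2. Hox genes lie in clusters, so neighbours can share a peak within 20 kb, while Fisher's exact test treats them as separate units. Why the Hox genes changed little was not tested, and their expression level was not weighed.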
